A study of Mus musculus with 16 samples.

How the data were processed

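The series examined the odorant response of the mouse olfactory mucosa with S100a5-tauGFP mice, in which the promoter of S100a5, a calcium-binding protein gene of active olfactory sensory neurons, drives a green fluorescent protein (GFP). Per the labels, 24 mice of both sexes aged 7 to 12 weeks were kept singly in clean-air chambers for 40 hours under an air flow of 3.1 L/min. From hour 26 they received a 10-second pulse every 20 min, either of the odorant, which the labels name indole/ionone, or of filtered air as vehicle. The ionone isomer, the doses and whether both odorants were given as a mixture are not given in the sources used here, so no comparison between the odorants was possible. The dissociated mucosa of 3 mice at a time was sorted into GFP+ and GFP- cells. This gave 16 samples from 8 pools, 4 pools per arm, each with 1 GFP+ and 1 GFP- sample. Each sample was labelled from 50 to 100 ng of total RNA and hybridised to a Clariom S array.

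The deposited values were taken as log2. Per the labels they were made with Affymetrix Expression Console, whose version is not given in the sources used here. The labels do not state the scale, and the base of the logarithm was inferred from the range of the values, which ran from about 2 to about 19. Background correction, normalization and probe summarization are not given in the sources used here. The values were not centred per gene. The quartiles of the arrays were close to each other, as after normalization between arrays. Median log2 levels ran from 6.05 to 6.39. In the odor pools they were 6.15, 6.11, 6.05 and 6.07 in GFP+ samples of replicates 1 to 4 and 6.33, 6.32, 6.39 and 6.24 in GFP- samples. In the vehicle pools they were 6.17, 6.07, 6.11 and 6.20 in GFP+ samples and 6.32, 6.25, 6.31 and 6.27 in GFP- samples. Each array held values of 28846 probes. Of these, 19572 had 1 gene symbol, 0 had several and 9274 had none in the platform annotation used here. All 19572 matched a RefSeq gene of the mouse assembly GRCm38.p6 by gene identifier, and that assembly was used for names, synonyms and the order of neighbouring genes. For the 55 genes with several probes, the probe with the highest mean over all 16 arrays stood for the gene, which left 19505 genes, among them 1080 odorant receptor genes.

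The pool of each sample was taken from the pool code in its title. The titles give the number 3 to a pair of vehicle pools, and the later of these was numbered 4 here. Within a pool, the GFP+ and GFP- samples deviated from their group means together, with correlations from 0.109 to 0.249 across genes, and in 8 of 8 pools the other fraction of the same pool correlated best among the pools of its arm. The difference of GFP+ and GFP- log2 levels within each pool was therefore the unit of the enrichment tests. Replicate numbers are also shared between odor and vehicle pools. The labels do not say that they mark shared handling, and all pool codes carry the same day. In GFP+ samples the deviations of same-numbered pools correlated at 0.114 to 0.242 over the 4 numbers, so the numbers were taken as pairing these samples. The GFP+ comparison as reported did not enter this pairing, and a block by number was run as an alternative. P-values measure the spread between pools of 3 mice.

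Tests used limma 3.58.1 in R 4.3.3. The enrichment difference, odor minus vehicle, and the enrichment within each arm came from a fit to the 8 within-pool differences. Odor was compared with vehicle separately in the 8 GFP+ and the 8 GFP- samples, without the replicate number as a block. Each SE of a log2 difference came from its fit, with 1 moderated variance per gene shared by both arms. It is therefore not the spread among the pools of 1 arm alone. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 19505 genes and, for the odorant receptors, also over the list alone, with a threshold of 0.05. A count of receptors passing all 3 criteria was fixed as well, namely a higher enrichment in odor pools, a higher level in GFP+ cells of odor pools and enrichment in GFP+ cells of odor pools. The test was tried on simulated data built from these arrays. Except where 10 receptors were changed, each simulation of odor against vehicle changed 50 receptors at each size, and other genes with them. The fits were to 19505 genes. In the enrichment difference, 29.4% of receptors given a log2 change of 1 and 82.6% of those given 2 were recovered. Recovery fell to 62.0% when 10 receptors changed by 2. False calls among receptors averaged 7.7 and 1.3 per simulation in these cases, more than the threshold of 0.05 would allow. In GFP+ cells 38.0% of receptors given a change of 1 and 6.6% of those given 0.5 were recovered. In GFP- cells these shares were 31.4% and 5.0%. A change of only 10 receptors was not tried in GFP+ or GFP- cells, and recovery may be lower there. For the enrichment within odor pools, 51.5% of genes changed by 1 and 91.4% of those changed by 2 were recovered. Within vehicle pools these shares were 49.7% and 90.9%. These simulations changed 100 genes at each size, far fewer than the 3620 genes called in odor pools or the 3835 in vehicle pools. Recovery with so many changed genes was not tried.

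A total of 35 gene lists was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. They covered odorant, class I odorant, trace amine-associated and vomeronasal receptors, sensory neuron states and functions, other cell types of the mucosa, blood cells, and stress and metabolic pathways. Of 503 list members fixed by symbol, 445 were measured by name. Class I receptors were the 120 receptors of sequence families 1 to 42 among the RefSeq synonyms, which gave a family for 1058 receptors. This rule was set after the annotation had been seen, and before any level had been examined.

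Groups, designs, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule named, for the enrichment difference and the GFP+ comparison, the receptors of smallest p past the threshold, or the 5 of smallest p as not passing where fewer than 5 passed. For GFP+ against GFP- cells it named the 10 largest differences each way past the threshold with the same sign in all 4 pools. For GFP- cells it named the 5 of smallest p each way, and from any list up to 4 members of smallest p. S100a5, Omp, Gap43, Fos, Kirrel2, Kirrel3 and Cyp2g1 were always named. Xist, also in the rule, was not named in the probe annotation used here. Other genes, such as Egr1, Pcdh10, Lrrc3b and Plcxd3 where a comparison's rule did not reach them, and the members of odor pool lists given in the text from among the 4 of smallest p, were chosen after their values had been seen. The alternatives were median centring, quantile normalization, a filter at 4.28 (the 25th percentile of probe means), a trended and robust prior, array weights, the mean of all probes, an ordinary t-test per gene (without moderated variances), pools as no block or as a random block, the replicate number as a block, and leaving out each pool in turn. Leaving out both pools numbered 3 and the replicate number as a block in the enrichment difference and in the list test of GFP+ cells were added after the data had been seen.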

Results

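The Kentucky assay looks for the odorant receptors of neurons that respond to an odor in freely behaving mice, by comparing receptor mRNA in GFP+ cells, sorted for the activity-driven S100a5-tauGFP reporter, between odor-exposed and control mice. Here 4 pools of 3 mice were exposed to indole/ionone and 4 pools to filtered air, and GFP+ and GFP- cells of each pool were measured on Clariom S arrays, 16 in all. Arrays of the same group correlated at 0.974 to 0.987 across probes and arrays of different fractions at 0.946 to 0.965. The first principal component held 71.3% of the variance and separated the fractions, with GFP+ samples at or below -61.5 and GFP- samples at or above 53.2. The GFP- sample of odor replicate 3 lay at 58.9 on the second component, whose highest value in the other samples was 24.6. No pair of arrays held identical values. In the pools numbered 3 of both arms, the Y-linked genes Eif2s3y, Uty and Kdm5d lay at 2.76 to 4.09 in both fractions, against 6.42 to 12.09 in the other pools.

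What the GFP gate separated was asked first in odor-exposed mice. S100a5, the gene whose promoter drives the reporter, was higher in GFP+ than in GFP- cells by 1.30 ± 0.17 on the log2 scale (SE, n = 4 pools, adjusted p = 1.84e-04), with levels of 16.30 ± 0.15 and 14.99 ± 0.44 (SD). Omp, the marker of mature olfactory sensory neurons, did not differ beyond its error, at 0.06 ± 0.12 (adjusted p = 0.800), and at levels of 18.50 and 18.44 it lay near the top of the scale. Of the 12 genes listed as raised by activity in sensory neurons, 10 were higher in GFP+ cells (list adjusted p = 2.73e-06, adjusted p = 0.0479 with an estimated correlation). S100a5, on whose promoter the sort rests, is 1 of these 10, and the list was not tested without it. The 10 also included the protocadherin gene Pcdh10 at 1.85 ± 0.19, Lrrc3b at 1.76 ± 0.20, Plcxd3 at 1.21 ± 0.15 and the adhesion gene Kirrel2, which acts in the sorting of axons into glomeruli, at 0.94 ± 0.17. Kirrel3, its counterpart in less active axons, differed by -0.34 ± 0.14 and did not pass (adjusted p = 0.114).

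**Figure D1:**
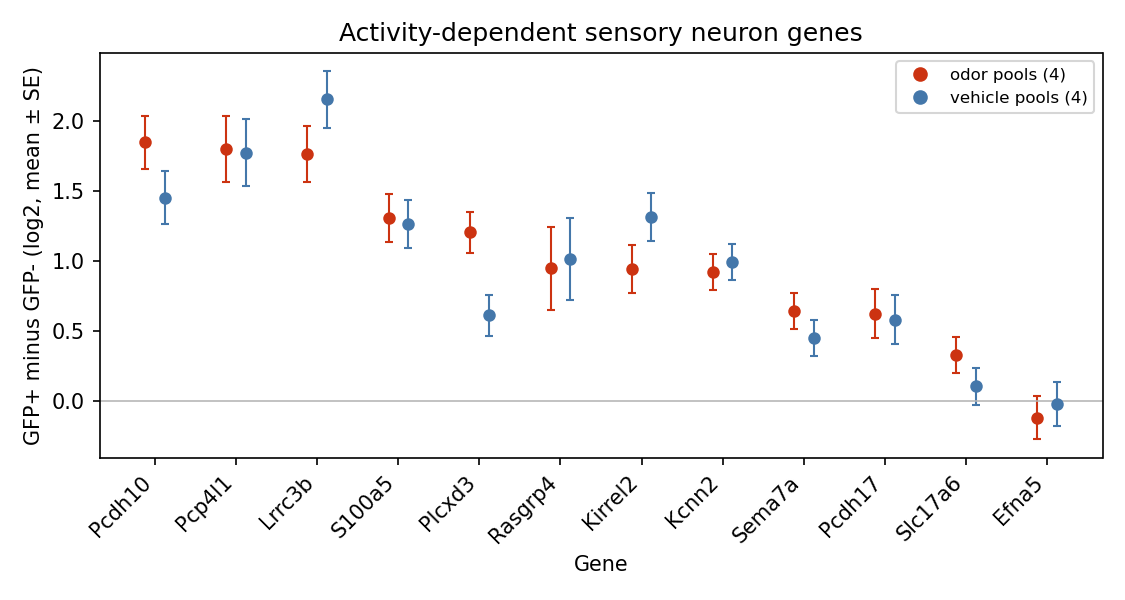
GFP+ minus GFP- log2 difference of the 12 measured activity-dependent sensory neuron genes, as mean over 4 odor pools (red) and 4 vehicle pools (blue). Bars are the moderated SE of the fit, which both arms share. S100a5 lies at 1.30 in odor pools and 1.27 in vehicle pools, and Pcdh10 at 1.85 and 1.45.

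Odorant receptor genes differed in both directions in odor pools. Of 1080 receptors, 468 were higher and 248 lower in GFP+ cells over all genes, and 513 and 285 adjusted over the list alone. Large positive differences were those of Olfr536 at 6.21 ± 0.27, Olfr309 at 5.83 ± 0.19, Olfr494 at 5.77 ± 0.31, Olfr533 at 5.48 ± 0.27 and Olfr1099 at 5.47 ± 0.20, followed by Olfr481, Olfr372, Olfr110, Olfr490 and Olfr613. At the other end, Olfr1507 differed by -8.18 ± 0.21, with levels of 6.06 ± 0.85 in GFP+ and 14.24 ± 0.49 in GFP- cells, and Olfr390 by -8.16 ± 0.39. In GFP- cells Olfr494, Olfr481, Olfr372, Olfr490 and Olfr613 had mean levels of 4.80 to 5.62, and in GFP+ cells Olfr390 one of 4.84, under the medians of the antigenomic background probes on those arrays (5.66 to 5.99 in GFP- and 5.78 to 6.01 in GFP+ samples). Their differences may therefore be limited by the background, and the order among receptors was not set. The list as a whole was higher with a median of 0.47 (adjusted p = 0.00793, adjusted p = 0.406 with an estimated correlation), a call that ended with median centring (adjusted p = 0.747). Class I receptors, the family shared with fish, were higher with a median of 0.57, 52 of 120 up and 14 down (adjusted p = 2.79e-04, adjusted p = 0.262 with an estimated correlation).

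Markers of blood cells and of several epithelial cell types were lower in GFP+ cells. All 13 neutrophil markers were lower, with a median of -7.86 (adjusted p = 1.84e-26, adjusted p = 0.0108 with an estimated correlation). Ngp, a neutrophil granule protein, differed by -10.41 ± 0.25, the siderophore-binding lipocalin Lcn2 by -10.17 ± 0.19, the resistin-like Retnlg by -10.02 ± 0.26 and S100a8, a calprotectin subunit, by -9.46 ± 0.26. Chil3, S100a9, Mmp8 and Ly6c2 also had large negative differences. In GFP+ cells Retnlg (5.62), S100a8 (5.34), Chil3 (5.56), Mmp8 (4.24) and Ly6c2 (4.04) lay under the background medians of 5.78 to 6.01. The size and order of these differences may be limited by the background. Levels in GFP+ cells lay under the medians for 1208 of the 2068 genes called lower there. Markers listed for lymphocytes were lower in 11 of 11 (Ptprc, shared with other leukocytes, -5.94 ± 0.15, Il7r -4.20 ± 0.35, adjusted p = 0.0108 with an estimated correlation). Macrophage markers were lower in 9 of 13 (Lyz2, the lysozyme of myeloid cells, -5.98 ± 0.23, adjusted p = 0.0479 with an estimated correlation). Erythroid markers were lower in 5 of 6, with the anion exchanger Slc4a1 at -3.79 ± 0.21 and the carbonic anhydrase Car1 at -6.55 ± 0.49 (adjusted p = 7.11e-07, adjusted p = 0.0787 with an estimated correlation). Of the lists for epithelial cells, that of microvillar and brush cells had 13 of 14 markers lower, such as the cation channel Trpm5 at -3.77 ± 0.26 and Alox5ap, also found in leukocytes, at -4.88 ± 0.32 (adjusted p = 0.0150 with an estimated correlation). Globose basal and proliferating cell markers were lower in 12 of 14, among them Mki67, found in dividing cells of any type, at -6.19 ± 0.25 and the receptor Kit at -3.92 ± 0.17 (adjusted p = 0.0410 with an estimated correlation).

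Sustentacular cell markers were lower in 8 of 15, with Krt18 at -3.68 ± 0.29 and the detoxifying enzyme Cyp2a5 at -1.85 ± 0.14 (adjusted p = 3.18e-08, adjusted p = 0.0479 with an estimated correlation). Cyp2g1, another detoxifying enzyme of the mucosa, differed by -1.34 ± 0.14. Immature sensory neuron markers were lower in 7 of 18. These included the growth cone gene Gap43 at -2.38 ± 0.17, the transcription factor Nhlh1 at -4.97 ± 0.26 and Dpysl3 at -3.80 ± 0.16 (list adjusted p = 9.08e-06, adjusted p = 0.0734 with an estimated correlation). Sensory neurons of the guanylyl cyclase D type had 4 of 11 listed markers lower, with Ms4a6c, also found in myeloid cells, at -3.57 ± 0.19 and Pde2a at -3.57 ± 0.20 (adjusted p = 0.0479 with an estimated correlation). Immediate early genes, the first transcripts made after stimulation, were lower in 16 of 23, with Fos at -4.32 ± 0.20 (15.45 ± 0.45 in GFP- cells), Egr1 at -5.71 ± 0.14, Btg2 at -5.47 ± 0.21 and Fosb at -5.27 ± 0.24 (adjusted p = 4.98e-17, adjusted p = 0.0108 with an estimated correlation). Dissociation stress genes, which share Fos and Egr1 with that list, were lower in 8 of 15, with Zfp36 at -5.02 ± 0.21 and Ier3 at -4.04 ± 0.17 (adjusted p = 0.0303 with an estimated correlation).

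Further lists passed with the preset correlation and not with an estimated correlation. Bowman's gland markers were lower in 5 of 14, led by Sox9 at -4.29 ± 0.18 (adjusted p = 0.262 with an estimated correlation). Horizontal basal cell markers were lower in 4 of 10, led by Sox2 at -1.86 ± 0.18 (adjusted p = 0.204 with an estimated correlation). Xenobiotic metabolism genes were lower in 11 of 28, with Cyp1a2 at -1.93 ± 0.15 and Cyp2a4 at -1.60 ± 0.16 (adjusted p = 0.292 with an estimated correlation). Cytosolic ribosomal protein genes were lower with a median of -0.15 and 1 of 63 past the threshold, Rplp0 at -1.37 ± 0.31, whose call ended without odor replicate 1 (adjusted p = 0.0523) or 4 (adjusted p = 0.0535), and for the list adjusted p = 0.741 with an estimated correlation. Respiratory ciliated cell markers were higher in 5 of 13, with Ccdc113 at 1.13 ± 0.17 and the flagellar Tekt4 at 0.83 ± 0.20 (adjusted p = 0.101 with an estimated correlation). Vomeronasal receptors were higher in 10 of 319, among them Vmn1r125 at 0.74 ± 0.14 (list adjusted p = 0.302 with an estimated correlation). Adjusted over the list alone limma called 0 of them, with 38 at an unadjusted p under 0.05 and 0 without moderated variances. Oxidative phosphorylation genes were higher in 1 of 28, Ndufb8 at 0.60 ± 0.14 (list adjusted p = 0.608 with an estimated correlation). Synaptic vesicle and glutamate release genes were higher in 3 of 21, with Syn2 at 0.70 ± 0.15, and 1 lower (list adjusted p = 0.608 with an estimated correlation). The synaptic call also ended with median centring (adjusted p = 0.0550).

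The other lists did not pass in odor pools. Olfactory transduction and adaptation genes had 3 members higher, among them the sodium-calcium exchanger Slc8a1 at 1.16 ± 0.16, and 2 lower, among them the G protein regulator Rgs2 at -5.53 ± 0.23 (list adjusted p = 0.325). Calcium-binding genes had 3 higher, with Pcp4l1 at 1.80 ± 0.24, and 3 lower, with calretinin, Calb2, at -4.29 ± 0.13 (list adjusted p = 0.981). Mature sensory neuron markers had 2 of 22 higher, with the calmodulin-dependent phosphodiesterase Pde1c at 0.67 ± 0.12, and 1 lower, Nrgn at -0.58 ± 0.14 (list adjusted p = 0.0969). Of 14 trace amine-associated receptors 8 were higher, with Taar9 at 2.97 ± 0.27, and 5 lower, with Taar2 at -4.75 ± 0.34 (list adjusted p = 0.600). Neuronal guidance and adhesion genes had 8 of 25 higher, among them Pcdh8 at 1.40 ± 0.17 (list adjusted p = 0.0684). Activity-suppressed guidance genes went both ways, with the ephrin receptor Epha5 at 0.68 ± 0.18 and the repulsive cue Sema3a at -0.62 ± 0.16 (list adjusted p = 0.981). The chaperone cofactor Dnajb9, at 0.55 ± 0.17, was the member past the threshold among unfolded protein response genes (list adjusted p = 0.981). Srxn1, a target of Nrf2, differed by 1.05 ± 0.17 (list adjusted p = 0.437), Sox10 of ensheathing glia by -1.24 ± 0.20 (0.518), the endothelial Pecam1 by -0.69 ± 0.15 (0.304) and the matrix gene Dcn of stromal cells by -0.89 ± 0.18 (0.129), while list adjusted p was 0.104 for aryl hydrocarbon receptor targets and 0.325 for sex-linked genes.

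Small differences among these did not hold in every alternative. Dnajb9 kept its call in 6 of 18 and lost it without odor replicate 1 (adjusted p = 0.113), 2 (0.108), 3 (0.109) or 4 (0.107) or vehicle replicate 2 (0.0617) or 4 (0.0569). Sema3a kept its call in 9 of 18 and lost it with median centring (0.0719), with quantile normalization (0.0586) and without odor replicate 1 (0.0887), 2 (0.0514) or 3 (0.0863). Epha5 kept its call in 14 of 18 and lost it without odor replicate 1 (0.0514), 2 (0.0968) or 4 (0.0686). Nrgn kept its call in 14 of 18 and lost it with median centring (0.0805), with quantile normalization (0.0855) and without odor replicate 1 (0.0600) or 4 (0.0731). Tekt4 kept its call in 15 of 18 and lost it without odor replicate 3 (0.0542), and Vmn1r125 in 16 of 17, losing it with pools not entered as a block (0.0711).

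In all, limma called 3620 of 19505 genes in odor pools, 1552 higher and 2068 lower in GFP+ cells. Without 1 odor pool it called 2677 to 2990, and the number higher fell to between 972 (without replicate 1) and 1112 (without replicate 2). With median centring the count was 8224, 6458 higher and 1766 lower, so that 78.5% of calls were higher in place of 42.9%, and the median difference of all genes moved from 0.115 to 0.338.

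**Figure D2:**
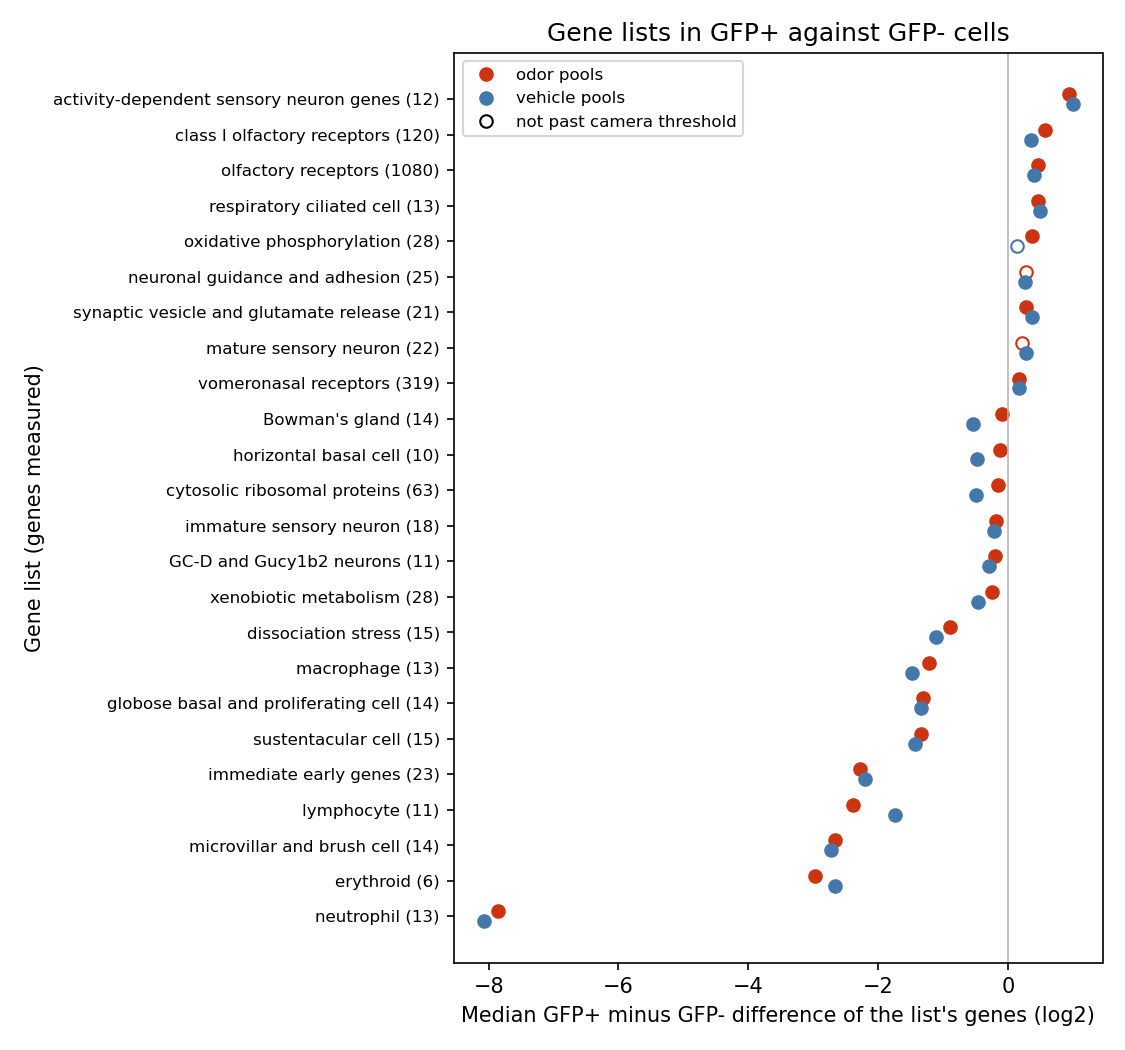
Median GFP+ minus GFP- log2 difference over the genes of each list, in 4 odor pools (red) and 4 vehicle pools (blue), for the 24 lists past the camera threshold in at least 1 arm, with the number of genes measured in parentheses and open circles where the list did not pass. Neutrophil markers lie lowest at -7.86 in odor and -8.07 in vehicle pools, and activity-dependent genes highest at 0.94 and 1.00.

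The same separation was asked of mice given filtered air. S100a5 was higher in GFP+ cells by 1.27 ± 0.17 (SE, n = 4 pools, adjusted p = 2.28e-04), Kirrel2 by 1.32 ± 0.17, Lrrc3b by 2.16 ± 0.20, Pcdh10 by 1.45 ± 0.19 and Plcxd3 by 0.61 ± 0.15, a call that ended without vehicle replicate 1 (adjusted p = 0.0629) or 4 (0.0609). Of the 12 activity-dependent genes, S100a5 again among them, 10 passed (list adjusted p = 9.82e-06, adjusted p = 0.0608 with an estimated correlation). Omp differed by 0.09 ± 0.12 (adjusted p = 0.678), with vehicle replicate 2 apart from the rest. Olfr536 was higher by 5.84 ± 0.27, with Olfr494 at 5.73 ± 0.31, Olfr309 at 5.54 ± 0.19, Olfr110 at 5.50 ± 0.22 and Olfr481 at 5.13 ± 0.20, followed by Olfr533, Olfr1093, Olfr372, Olfr613 and Olfr522. In GFP- cells of these pools Olfr494, Olfr481, Olfr372, Olfr613 and Olfr1093 had mean levels of 4.55 to 5.50, under the background medians of 5.63 to 6.05. Their differences may be limited by the background. Large negative differences were again those of Retnlg at -10.08 ± 0.26, Ngp at -9.86 ± 0.25 and Lcn2 at -9.81 ± 0.19, with Chil3, S100a8, Ly6c2, S100a9, Mmp8, Ly6c1 and Ctse. As in odor pools, 1209 of the 2107 genes called lower had GFP+ levels under the background medians of 5.76 to 5.97. Fos differed by -4.56 ± 0.20, Egr1 by -5.47 ± 0.14, Gap43 by -2.77 ± 0.17, Cyp2g1 by -1.43 ± 0.14 and Kirrel3 by -0.23 ± 0.14, the last without passing (adjusted p = 0.288).

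In vehicle pools limma called 1728 genes higher and 2107 lower, with 467 and 276 receptors over all genes and 501 and 312 adjusted over the list alone. Without 1 vehicle pool the number higher fell to between 1010 (without replicate 1) and 1510 (without replicate 3), and was 1014 without replicate 2. The split was 45.1% higher, and 67.6% higher with median centring, which moved the median of all genes from 0.109 to 0.259. The receptor list was higher with a median of 0.40 (adjusted p = 0.0312, adjusted p = 0.479 with an estimated correlation) and class I receptors with 0.35 (adjusted p = 0.0128, adjusted p = 0.432 with an estimated correlation), and both calls ended with median centring (adjusted p = 0.587 and 0.134). Of the cell type lists, neutrophil (13 of 13), microvillar and brush cell (13 of 14), globose basal cell (12 of 14), macrophage (11 of 13), lymphocyte (9 of 11) and sustentacular cell markers (9 of 15) were lower, each with an adjusted p between 0.0184 and 0.0354 with an estimated correlation. Immediate early genes were lower in 17 of 23 (adjusted p = 9.77e-16, adjusted p = 0.0184 with an estimated correlation).

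Enrichment of the receptors was nearly the same in both arms, which use different mice. Across receptors, which are not independent replicates, it correlated at r = 0.984 and rho = 0.976. Adjusted over the list alone, 469 receptors were higher in GFP+ cells in both arms and 268 lower in both, where independent lists would share 238.0 and 82.3, and 0 were called in opposite directions by limma in the 2 arms. Differences ran from -8.18 to 6.21 in odor pools and from -8.03 to 5.84 in vehicle pools, and 59 receptors were over 8-fold higher and 111 over 8-fold lower in both arms. Over all genes, 2730 were called in the same direction in both arms.

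**Figure D3:**
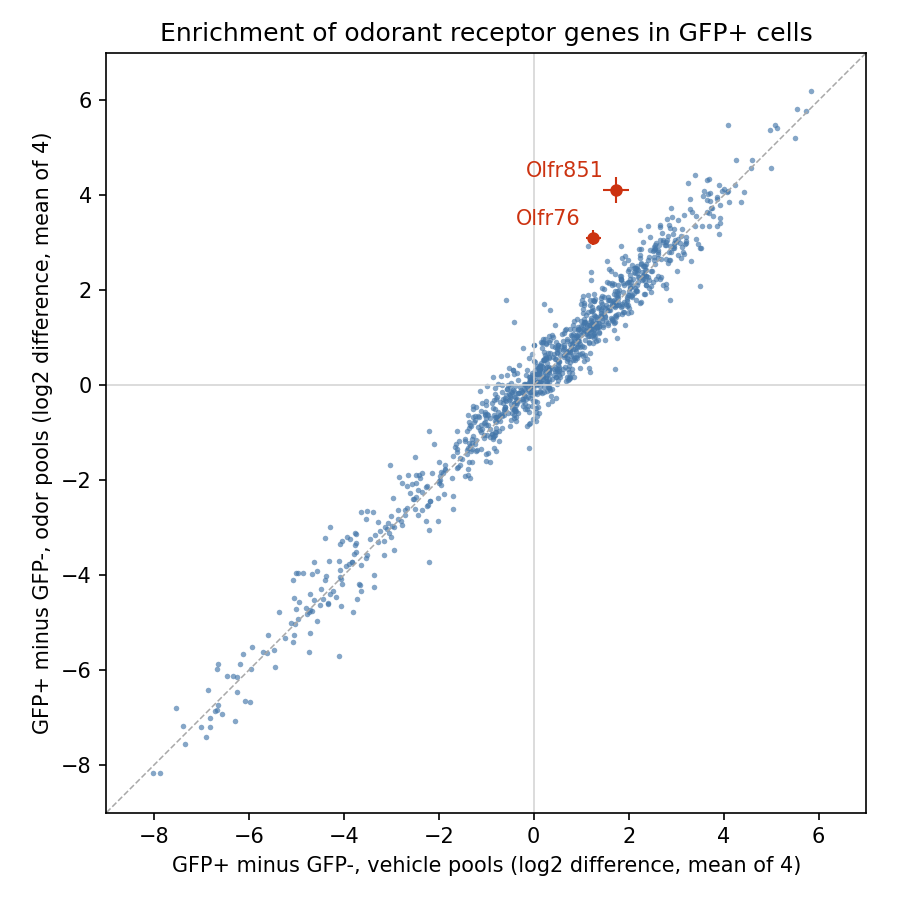
GFP+ minus GFP- log2 difference of the 1080 odorant receptor genes, mean of 4 vehicle pools against mean of 4 odor pools, with the line of equal enrichment dashed and Olfr76 and Olfr851 in red with SE bars. Receptors follow the line at r = 0.984, and Olfr76 lies at 1.26 in vehicle and 3.11 in odor pools.

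Receptors whose enrichment in GFP+ cells was larger after odor were the question of the design. Olfr76 was enriched by 3.11 ± 0.16 in odor pools and by 1.26 ± 0.16 in vehicle pools, a difference of 1.85 ± 0.22 (SE, 4 pools against 4, adjusted p = 0.00476 over the list alone and 0.0860 over all genes). In each odor pool, at 2.64 to 3.38, its enrichment exceeded that of each vehicle pool, at 1.02 to 1.59. Its level in GFP+ cells was 10.68 ± 0.14 after odor and 10.79 ± 0.25 after vehicle (SD), whereas in GFP- cells it was 7.57 ± 0.28 and 9.53 ± 0.33. Olfr851 was enriched by 4.12 ± 0.28 and 1.74 ± 0.28, a difference of 2.38 ± 0.39 (adjusted p = 0.0452 over the list alone and 0.817 over all genes). Its odor pools ran from 3.13 to 5.31 and its vehicle pools from 1.39 to 2.23.

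**Figure D4:**
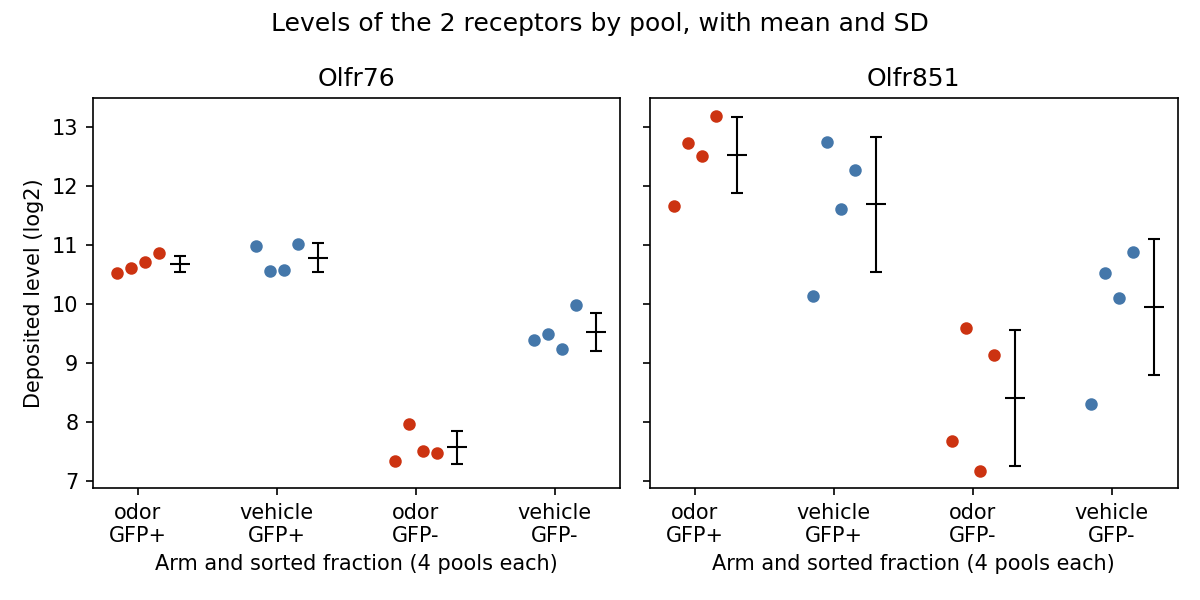
Log2 levels of Olfr76 and Olfr851 in each of the 4 pools per arm and fraction (points, odor red and vehicle blue), with mean and SD in black. In GFP- cells Olfr76 lies at 7.34 to 7.97 in odor pools and 9.24 to 9.99 in vehicle pools, while in GFP+ cells the arms overlap.

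Olfr282 (-1.23 ± 0.22, adjusted p = 0.0525 over the list alone), Olfr58 (1.80 ± 0.33, adjusted p = 0.0577) and Olfr616 (1.18 ± 0.24, adjusted p = 0.0901) came next and did not pass. Olfr282 passed with array weights (0.0422) and without vehicle replicate 2 (0.0388), Olfr58 without vehicle replicate 2 (0.0388) and with the replicate number as a block (0.0195), and Olfr616 without vehicle replicate 2 (0.0433). Olfr282 lay at 3.98 to 5.31 in all 4 groups, under the background medians of 5.63 to 6.05, and Olfr58 at 5.53 in GFP- cells of odor pools. S100a5 differed between the arms' enrichments by 0.04 ± 0.24, Pcdh10 by 0.40 ± 0.27, Kirrel2 by -0.38 ± 0.24 and Fos by 0.25 ± 0.28, none of which passed (adjusted p = 1.00 for each). At an unadjusted p under 0.05, 74 receptors differed, 56 more and 18 less enriched after odor, where 54.0 of 1080 would be by chance over both directions together. Over all genes limma called 0, with 654 at an unadjusted p under 0.05, fewer than the 1 in 20 of 19505 that chance would give. A test per gene without moderated variances also called 0. Olfr76 lost its call over the list with a trended and robust prior (adjusted p = 0.0590), a test without moderated variances (0.120) and without both pools numbered 3 (0.0538). Olfr851 kept its call in 7 of 19 alternatives and lost it with no block by pool (1.00), without moderated variances (0.750), with a random block by pool (0.678), a trended and robust prior (0.0852), the dim filter (0.0534), median centring (0.0503), without both pools numbered 3 (0.0795) and without odor replicate 1 (0.0909) or 4 (0.105) or vehicle replicate 1 (0.0932), 3 (0.115) or 4 (0.114), and 3 of the 35 splits of the 8 pools gave 2 or more receptors.

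Lists shifted little between the arms' enrichments. Cytosolic ribosomal protein genes were relatively more enriched after odor, by a median of 0.36 with 62 of 63 positive (adjusted p = 1.78e-07, adjusted p = 0.909 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.16 (adjusted p = 0.0354, adjusted p = 0.909 with an estimated correlation) and class I receptors of 0.12, 74 of 120 positive (adjusted p = 0.0482, adjusted p = 0.909 with an estimated correlation). All 3 calls ended without odor replicate 3, where 0 lists passed.

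Within GFP+ cells alone, the direct comparison of active neurons between odor and vehicle, no receptor passed. The smallest p belonged to Olfr1168, at -0.80 ± 0.15 (SE, 4 pools against 4, adjusted p = 0.234 over the list alone), Olfr1258 at 0.69 ± 0.16, Olfr926 at 0.80 ± 0.18, Olfr1434 at -0.79 ± 0.19 and Olfr452 at 0.78 ± 0.18 (adjusted p = 0.301 for each of these 4). The GFP+ levels of Olfr926 (5.22 and 4.42), Olfr1434 (3.92 and 4.71) and Olfr452 (4.86 and 4.08) after odor and vehicle lay under the background medians of 5.76 to 6.01, so that these 3 differences were between values not above those medians. Olfr76 differed by -0.10 ± 0.15 and Olfr851 by 0.83 ± 0.50. Pcdh10 had a level of 11.28 ± 0.37 after odor and 9.94 ± 0.26 after vehicle (SD), a difference of 1.34 ± 0.20 that did not pass (limma unadjusted p = 3.73e-05, adjusted p = 0.728). Kirrel2 differed by 0.60 ± 0.19, Lrrc3b by 0.78 ± 0.26, Plcxd3 by 0.56 ± 0.20, S100a5 by 0.22 ± 0.12 and Fos by 0.33 ± 0.28, none passing. As a list, the 12 activity-dependent genes were higher after odor with a median of 0.22 and 9 of 12 positive (adjusted p = 0.00246, adjusted p = 0.352 with an estimated correlation). Class I receptors (median 0.19, adjusted p = 0.00107, adjusted p = 0.999 with an estimated correlation), globose basal cell markers (median 0.14, adjusted p = 0.0276, adjusted p = 0.352 with an estimated correlation) and ribosomal protein genes (median 0.16, adjusted p = 6.35e-05, adjusted p = 0.999 with an estimated correlation) were higher too. Over all genes limma called 0, with 1070 at an unadjusted p under 0.05, where chance would give about 1 in 20 of 19505. A test per gene without moderated variances also called 0. Of the 1080 receptors limma called 0, with 77 at an unadjusted p under 0.05, where 54.0 would be by chance. Without moderated variances 0 were called, and leaving out vehicle replicate 2 gave 1.

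Within GFP- cells, which hold the remaining neurons and the other cells of the mucosa, Olfr76 fell after odor by 1.95 ± 0.21 on the log2 scale (SE, 4 pools against 4, adjusted p = 0.0292 over all genes and 0.00162 over the list alone). It was the only gene called by limma, and its level was lower in 4 of 4 odor pools than in each vehicle pool. Among other genes of smallest p, none passing, Olfr843 differed by -2.09 ± 0.44, Bpifb9a by -2.07 ± 0.50, Cpne6 by -0.86 ± 0.20 and Mpzl3 by -0.71 ± 0.18. Positive differences were those of the potassium channel gene Kcng1 at 1.36 ± 0.29, Sh2b2 at 0.81 ± 0.16, Cnmd at 0.79 ± 0.17, Elk3 at 0.74 ± 0.16 and Mettl4 at 0.69 ± 0.15 (adjusted p = 1.00 for each, rounded). Of these, Cpne6 (3.34 and 4.20) and Cnmd (5.63 and 4.83) lay under the background medians in both arms and Elk3 (5.27) in vehicle pools. Olfr843, at 5.90 in odor pools, lay among the background medians of 5.66 to 5.99 there, so the size of its difference may be limited by the background. Olfr851 differed by -1.55 ± 0.62, S100a5 by 0.18 ± 0.24, Pcdh10 by 0.94 ± 0.30, Kirrel2 by 0.98 ± 0.34 and Lrrc3b by 1.18 ± 0.37, without passing. Sustentacular cell markers were lower after odor with a median of -0.28 and 0 of 15 positive (adjusted p = 0.00231, adjusted p = 0.984 with an estimated correlation). Macrophage markers (median -0.19, adjusted p = 0.0310, adjusted p = 0.800 with an estimated correlation), oxidative phosphorylation genes (median -0.17, adjusted p = 0.00883, adjusted p = 0.984 with an estimated correlation) and ribosomal protein genes (median -0.20, adjusted p = 8.40e-04, adjusted p = 0.984 with an estimated correlation) were lower too, and 0 lists passed without vehicle replicate 1. The call of Olfr76 over all genes ended without moderated variances and without any 1 pool other than odor replicate 2, whereas over the receptor list alone it held in 8 of 8 cases of leaving out a pool and ended without moderated variances (adjusted p = 0.104).

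No receptor passed all 3 criteria together in limma. At unadjusted p under 0.05, 12 receptors met all 3 in the positive direction, and without moderated variances 0 passed after adjustment. The 3 criteria share the GFP+ values of odor pools, and no number by chance was worked out for the 12. Among them Olfr543, Olfr746, Olfr507 and Olfr830 had group means of 3.23 to 5.57, under the background medians of 5.63 to 6.05.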

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

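The tests of why Olfr76 and Olfr851 differed and the counts of other splits of the pools for the odor comparisons were chosen after the results had been seen.

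Olfr76 and Olfr851 stood out because their enrichment in GFP+ cells differed between odor and vehicle pools by the test of that difference, at 1.85 for Olfr76 and 2.38 for Olfr851. A smaller number of GFP+ neurons left in the GFP- samples of odor pools would have lowered every receptor of such neurons there, yet the 499 other receptors enriched in GFP+ cells of vehicle pools changed by a median of -0.035 in GFP- cells (quartiles -0.254 and 0.196), and 1 of them fell as far as Olfr76. The vehicle GFP- values both chose the 499 receptors and entered their change, which can shift that change upward. With median centring and quantile normalization the smallest difference of Olfr76 and Olfr851 was still 1.922. The quartiles of the arrays were already close, so these steps could move the difference little, and this test cannot exclude other effects of scaling. A candidate explanation that stays open is that neurons with Olfr76 passed from the GFP- to the GFP+ fraction in odor-exposed mice. In GFP+ cells Olfr76 differed by -0.105 (95% interval -0.44 to 0.23), and without the number of cells sorted into each fraction this cannot be told apart from a lower level in the neurons that stayed GFP-.

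Other splits of the 8 pools bear on chance. With 2 receptors called in the enrichment difference, 3 of the 35 splits gave as many and the highest other gave 5, so chance could not be excluded. Of the 8 splits that part all same-numbered pools, 1, the real one, gave as many and the highest other gave 0. That is too few splits for a share under 0.05. For the fall of Olfr76 in GFP- cells, called over all genes, 1 of 35 splits, the real one, gave a gene and the highest other gave 0, so chance is excluded for that count only if all 8 pools can be exchanged. Same-numbered GFP- samples correlated at 0.327, 0.332 and 0.186 for numbers 1, 3 and 4, and of the 8 splits that part all same-numbered pools 1, the real one, gave a gene and the highest other gave 0, too few splits for a share under 0.05. The share of 1 in 35 is also 1 of 10 such counts, and the call ended in 7 of 8 fits without a pool. Among receptors alone 5 of 35 splits gave at least 1, with up to 9, so chance stays open for the fall of Olfr76 itself. In the 8 splits that part same-numbered pools, 1, the real one, gave a receptor there and the highest other gave 0, again too few splits to decide. A count of 0 is matched by every split, so nothing follows about chance from the 0 genes of the enrichment difference (35 of 35 splits, highest 1), the 0 genes and 0 receptors of GFP+ cells (35 of 35, highest 1 and 17) or the 0 receptors by all 3 criteria (35 of 35, highest 1). The 17 receptors in GFP+ cells came when the pools numbered 1 and 2 were set against those numbered 3 and 4, a count that points to structure among the pools. The 8 splits that part all same-numbered pools gave 0 receptors there. Lists were called as often in 25 of 35 splits for the enrichment difference (3 real, highest other 12), in 20 for GFP+ cells (4 and 10) and in 31 for GFP- cells (4 and 17), so chance could not be excluded for these lists. For GFP+ against GFP- cells, exchanging fractions within pools gives only 8 arrangements, too few for a share under 0.05. In odor pools 1 of them, the real one, gave 3620 genes and 22 lists, with highest others of 0 and 17, and in vehicle pools 1 gave 3835 genes and 23 lists, with highest others of 0 and 22.

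Single pools lay far from the other 3 of their group in 5 of 186 groups examined, where chance gives about 1 in 20, or 9.3. In odor replicate 4 the GFP+ minus GFP- difference of Olfr481 was 5.93 against 5.19 to 5.28 in the others, and that of Olfr677 was -8.73 against -6.78 to -6.58. In odor replicate 3 the difference of Syn2 was 0.24 against 0.81 to 0.91. In vehicle pools, Omp had 0.35 in replicate 2 against -0.01 to 0.01, and Pcdh10 had 2.14 in replicate 1 against 1.18 to 1.28.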

How the results depend on the processing

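The fits without both pools numbered 3, those with the replicate number as a block in the enrichment difference, and the blocked list test of GFP+ cells were chosen after the data had been seen. All alternatives set in advance could be run.

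Among named genes, direction and side of the threshold were the same in 1529 of 1565 comparisons with alternatives for odor pools (36 lost their call) and in 590 of 594 for vehicle pools (3 lost it, 1 reversed). They were the same in 234 of 234 within GFP+ cells, in 267 of 269 within GFP- cells and in 147 of 171 for the enrichment difference, where 15 lost a call, 5 gained one and 4 reversed. Olfr76 kept its call in the enrichment difference in 16 of 19 alternatives (adjusted p from 5.35e-04 to 0.120, log2 difference 1.76 to 2.00) and in GFP- cells, over the receptor list alone, in 17 of 18.

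For receptors in the enrichment difference, 2 in the fit as reported, median centring, the dim filter, no block by pool and a random block by pool gave 1, Olfr76. A trended and robust prior and the ordinary t-test gave 0, array weights 5, the replicate number as a block 5, and the fit without both pools numbered 3 gave 0. Leaving out 1 pool gave 1 to 6, with 6 without vehicle replicate 2 and 1 without odor replicates 1 or 4 or vehicle replicates 1, 3 or 4. Over all genes, no block and a random block each gave 1 in place of 0. The fewer pools explain part of the loss by construction, and otherwise the cause was not tested.

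In odor pools median centring gave 8224 genes in place of 3620, since it moved the median of all genes from 0.115 to 0.338. In GFP+ cells 0 or 1 receptor was called without 1 pool, with 1 only without vehicle replicate 2. In GFP- cells Olfr76 was the 1 gene called. The ordinary t-test and the fit without both pools numbered 3 gave 0, and leaving out 1 pool gave 0 or 1, with 1 only without odor replicate 2. Among receptors there the t-test gave 0 and a random block 2, Olfr76 and Olfr843. The cause was not tested.

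With an estimated correlation 0 of 3 lists passed in the enrichment difference, 10 of 22 in odor pools, 9 of 23 in vehicle pools, 0 of 4 in GFP+ and 0 of 4 in GFP- cells, and with fry 0 in the enrichment difference, 26 in odor pools, 24 in vehicle pools, 0 in GFP+ and 0 in GFP- cells. Leaving out 1 pool gave 0 to 5 lists in the enrichment difference (0 without odor replicate 3, 1 without vehicle replicate 4, 5 without vehicle replicate 1 or 2), 2 to 7 in GFP+ cells (7 without odor replicate 1, 2 without vehicle replicate 1) and 0 to 10 in GFP- cells (0 without vehicle replicate 1, 7 without vehicle replicate 2, 9 without odor replicate 1, 10 without vehicle replicate 3). Without both pools numbered 3, GFP- cells gave 12. In GFP+ cells, where the replicate numbers pair the samples, a block gave the same counts of 0 genes, 0 receptors and 4 lists. In GFP- cells same-numbered deviations correlated at 0.327, 0.066, 0.332 and 0.186 for numbers 1 to 4, and in the differences at 0.179, 0.097, 0.305 and 0.109. Number 2 in GFP- cells and number 4 in the differences correlated better with another pool (0.148 and 0.144), so pairing was not assumed there and is not excluded for the other numbers. The pools numbered 3 of both arms also shared low Y-linked levels, at 2.76 to 4.09. The enrichment difference and the GFP- comparison as reported did not enter the replicate number. The cause was not tested.

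S100a5 in the enrichment difference, at 0.04 and not past the threshold, reversed with array weights (-0.054), without both pools numbered 3 (-0.009), without odor replicate 3 (-0.146) and without vehicle replicate 1 (-0.051), and reached 0.175 without vehicle replicate 3. Omp in vehicle pools ran from -0.001 without vehicle replicate 2 to 0.238 over the 18 alternatives. Median signal of the 23 antigenomic background probes was 5.63 to 6.05, near the median of all probes, which may limit what dim genes can show. The Y-linked genes Eif2s3y, Uty and Kdm5d lay lower, at 2.76 to 4.09, in the pools numbered 3. A level under these medians is therefore not always the lowest a gene can reach.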

Other observations

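The tests of receptor families, receptor classes and abundance, of female mice and of chromosome stretches, and the count over 10 clock genes were chosen after the results had been seen, as were the families named here and the added condition for excluding a time of day.

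Receptors of a sequence family tended to be enriched alike in mice given filtered air. In GFP+ against GFP- cells of vehicle pools, family 106 had a median difference of 2.73 over 13 receptors, 11 of them above 0, family 283 a median of 2.27 over 12, family 253 of 2.14 over 10 and family 224 of 1.68 over 10, all above 0 (1.32 to 3.72). Family 225 had a median of -3.09 over 11 receptors, 2 of them above 0, family 266 of -2.18 over 8 and family 135 of -1.45 over 17. Over 158 families with 994 receptors, the share of variance between families was 29.6%, against a mean of 15.8% and a highest value of 22.4% in 10000 shuffles (permutation p = 1e-04, the smallest they can give). Genes are not independent replicates, and probes shared between similar receptors, which were not tested, may add to this share, so that a common enrichment within families is a hypothesis, which counts of sequencing reads unique to each receptor would decide.

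Other properties of the receptors were compared with their enrichment. Enrichment in vehicle pools was nearly unrelated to a receptor's mean level, at r = 0.09 and rho = 0.13 across receptors, which are not independent replicates, but levels of different probes measure abundance only roughly, so abundance stays open and the bound that would have excluded it was wrong. Class I receptors had a median of 0.35 and the 938 class II receptors with a known family 0.41, a difference of -0.052 (permutation p = 0.879). The bootstrap interval of 95%, from -0.27 to 0.32, leaves a small difference between the classes open.

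Immediate early genes such as Fos, Egr1 and Btg2 were lower in GFP+ cells although the reporter marks active neurons, and cells other than mature neurons in the GFP- samples are a candidate source. Over the 8 GFP- samples, with arm means removed, the mean of these genes rose with microvillar and brush cell markers (r = 0.82, permutation p = 0.0106, adjusted p = 0.0317, rho = 0.93 with p = 0.00223, r = 0.89 without the 2 farthest samples). With neutrophil markers r was 0.75 (permutation p = 0.0351, adjusted p = 0.0527 over the 3 relations, rho = 0.76 with p = 0.0368, r = 0.60 without the 2 farthest), which failed the correction. With immature neuron markers r was -0.07 (permutation p = 0.867, adjusted p = 0.867, rho = -0.12 with p = 0.793, r = 0.67 without the 2 farthest), which decides nothing. The permutations moved the centred values across both arms and did not keep same-numbered samples together. Such GFP- samples correlated at 0.066 to 0.332 over the 4 numbers, and a shared effect of the number was not tested. The p-values of these relations are therefore approximate and may be too small. The sort for GFP would leave such cells in the GFP- samples of odor pools, where Lcn2 lay at 17.18 ± 0.46, Ngp at 17.13 ± 0.55, Coch at 14.03 ± 0.89 and Alox5ap at 11.52 ± 0.76 (SD, n = 4), and induction of these genes by dissociation was not tested apart from them. Alox5ap is also found in leukocytes, and the marker lists were not tested against each other. The relations therefore do not tell microvillar cells and neutrophils apart as sources.

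The pools numbered 3 stood apart in both arms. In all 4 groups of samples, 660 genes were highest or lowest there in the same direction, 244 higher and 416 lower, where the other combinations of an odor and a vehicle pool gave 121 to 452, and among them were 69 receptors, 60 of them lower, against at most 25, such as Olfr910, higher by 1.34 to 2.07, and Olfr1204, at -2.20 to -1.75. The Y-linked genes Eif2s3y, Uty and Kdm5d lay at 2.76 to 4.09 there, under the background medians of 5.63 to 6.05, against 6.42 to 12.09 in the other pools. No Y-linked transcript was thus seen above background in the pools numbered 3. The X-linked genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x were highest there in 14 of 16 cases. Female mice in these pools are a candidate explanation for the 660 genes, and whether sex accounts for them was not tested apart from other differences. Another time of day at collection stays open, since Per1, Per2, Per3, Nr1d1 and Bhlhe41 were highest there in all 4 groups (Per2 by 0.89 to 1.97), as were 10 clock genes of that phase in 32 of 40 cases where chance gives 10, while Arntl, Npas2 and Clock, of the opposite phase, were lowest in 4 of 12, where chance gives 3, and the bound written beforehand lay too near chance to exclude it. Stretches of chromosome from another strain stay open too (8 neighbouring pairs among the 69 receptors, 4.3 in random sets, permutation p = 0.0565).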
